A study of Mus musculus with 6 samples.

How the data were processed

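RNA was measured in 6 libraries of mouse leukaemia cells that carried the MLL-AF9 fusion, 3 grown from LSK cells and 3 from granulocyte-macrophage progenitors (GMP). LSK cells are bone marrow cells without lineage markers that carry Sca-1 and Kit, a population rich in haematopoietic stem cells. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with the TruSeq RNA kit. The authors deposited 1 table of raw read counts per gene symbol, with 1 column for each library and no normalization. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1, DESeq2 and the build mm9 were used, with no role or order given. The gene annotation and the strand setting of the counting are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes may have been assigned to either, and genes with near-identical copies (Bcl2a1a and Bcl2a1d, the Oas1 genes, the adult beta-globin genes, the Klr and Clec2 families) are uncertain for the same kind of reason. Among named genes, exons of Gfi1, Bak1, Meis1, Cd34, Ciita, Col4a2 and Mybbp1a overlap those of another tested gene in the reference annotation. The table holds no coordinates, so none are printed. The reference annotations used here (RefSeq on GRCm38.p6 and GENCODE M21) belong to another build than mm9 and served for gene order, exon overlap, transcript length and GC content alone. Of the 13406 tested genes, 96.5% matched the RefSeq gene order and 97.7% had a transcript length and GC content.

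The table had 33924 gene rows, of which 12325 had 0 counts in all libraries. Total counts per library ran from 16640929 to 33885428. A gene with 0 counts could have had up to 3 counts, which is 0.180 CPM in the smallest library and 0.0885 CPM in the largest. All counting intervals are exact 95% intervals and cover only the counting error of the lower group. Library totals, and the CPM that 3 counts amount to, came from the deposited counts of all gene rows without TMM scaling.

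Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, libraries were scaled by TMM, and glmQLFit with robust estimation was followed by glmQLFTest on the 6 libraries, with no covariate. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p below 0.05. Log2 fold changes are LSK-derived minus GMP-derived, so that a positive value is higher in the LSK-derived libraries. CPM values are the deposited counts divided by the library's total over tested genes, scaled by its TMM factor, and multiplied by 1e6. They are given as mean ± SD over 3 libraries in each group. Log2 fold changes carry an approximate standard error (SE), the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. This SE is derived from the test and is not a standard error of the fitted coefficient. With few counts in a group, as for Mecom and Bcl11a, it can be smaller than counting error alone. For a gene with 0 counts in a group, the fold is a lower bound against 3 counts over that group. For 1 to 3 counts, a ratio is given with its counting interval. It divides the higher group's mean CPM by the lower group's pooled CPM, the latter without TMM scaling.

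Before the data were examined, 23 gene lists were fixed. The lists on the study's subject held haematopoietic stem cell genes, granule and progenitor genes, MLL fusion targets, p53 targets, anti-apoptotic genes, pro-apoptotic genes and the LSD1 complex. Marker lists covered monocytes, neutrophils, megakaryocytes and erythroid cells, mast cells and basophils, B cells, T and NK cells, dendritic cells, and stroma. The other lists held interferon, cell cycle, MYC and ribosome biogenesis, NF-kB, cytokine receptor, immediate early, endoplasmic reticulum stress and sex-linked genes. All but the sex-linked list were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over 22 lists. Beside it, camera with an estimated correlation and fry, a rotation test of a list's own direction, were run. Members were counted from the edgeR test over all tested genes, and again adjusted over the list alone.

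The genes named were chosen by a rule fixed at the same time. It took the 10 called genes with the largest change in each direction that had a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed gene models and antigen receptor segments. It also took up to 4 called members per list by smallest p, or up to 2 by expression where fewer than 2 passed, and 20 genes fixed by name. Named genes that this rule does not give complete a count of 5 or fewer or are marked in the text, and were chosen after their values were seen.

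The edgeR and camera steps were tested on simulated counts drawn from the real means and library sizes. For the comparison of LSK-derived with GMP-derived libraries, 13215 genes passed the filter. Of 100 genes changed 2-fold 63%, and of 100 genes changed 4-fold 90%, were called in the right direction. There were 17 false calls, a larger share of all calls than the adjusted p threshold of 0.05 aims at. The simulated changed list was called, and 0 of 20 unchanged lists were. All members of the changed list were raised by the same fold, so its call says little on lists whose members move both ways. The simulated lists were drawn at random and lack the correlation of real pathways. Principal components used TMM log2 CPM with a prior count of 2 over the 500 most variable genes. Distances between libraries were compared by an exact permutation over the 10 splits of 6 libraries into 3 and 3.

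The titles number the libraries 44, 45 and 46 in the LSK-derived group and 5, 11 and 19 in the GMP-derived group, so no number pairs libraries across groups and no block was fitted. Alternatives were other scalings (DESeq2 size factors, upper quartile), no filter and a filter of at least 2 CPM in 3 libraries, DESeq2 1.42.0, limma voom with and without sample weights, a minimum change of 1.5-fold, a threshold of 0.01, lists without shared genes, and leaving out each library in turn. Thinning to the smallest library and removal of length and GC trends were added after seeing the data. A sex covariate had been planned for the case that both sexes occurred within a group. It was not fitted: Xist, the transcript of the inactive X chromosome, had 1396 to 1875 CPM in all 6 libraries, and the Y-linked genes together had at most 1 count in a library.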

Results

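Gene expression was measured by RNA sequencing in mouse acute myeloid leukaemia cells that carried MLL-AF9, a fusion of the KMT2A (MLL) and MLLT3 (AF9) genes introduced by retrovirus. The fusion had been introduced into LSK cells, which are rich in stem cells, or into granulocyte-macrophage progenitors, which are committed to the myeloid lineage. The transformed cells had been transplanted into irradiated C57BL/6 mice, and leukaemia cells from the bone marrow of sick animals were kept in culture with the cytokines SCF, IL-3 and IL-6. Each group held 3 libraries, here named by their numbers in the titles (LSK 44, LSK 45 and LSK 46; GMP 5, GMP 11 and GMP 19). Total counts ran from 16640929 in LSK 44 to 33885428 in GMP 11. Expression is given as mean ± SD of 3 libraries in each group. Log2 fold changes (LSK-derived minus GMP-derived) are given with an approximate SE derived from the test, which is too small for some genes with few counts in a group. The labels do not say whether the 3 libraries of a group came from separate transductions or mice, so p-values measure only the spread between these libraries, which may be in part technical. The series title names the question: whether the cell in which a leukaemia arises bears on its readiness for apoptosis and on its response to inhibition of LSD1, a histone demethylase encoded by Kdm1a. No library is labelled as treated with an inhibitor, so the comparison is of untreated expression.

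The libraries separated by cell of origin. Over the 500 most variable genes, the first principal component held 83.7% of the variance and set the LSK-derived libraries apart from the GMP-derived ones, and the second held 8.13% and set GMP 5 apart from GMP 11 and GMP 19. The mean distance between libraries of different groups was 127, against 56.5 within the LSK-derived and 67.0 within the GMP-derived group. The between-group distance exceeded the within-group distance by 65.2, and an exact one-sided permutation test gave p = 0.1, the smallest p that 10 splits allow. The median SD of log2 CPM within a group was 0.134 in the LSK-derived and 0.160 in the GMP-derived libraries. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 9.70, so none was a copy of another, and this does not show that they are separate biological samples.

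**Figure D1:**
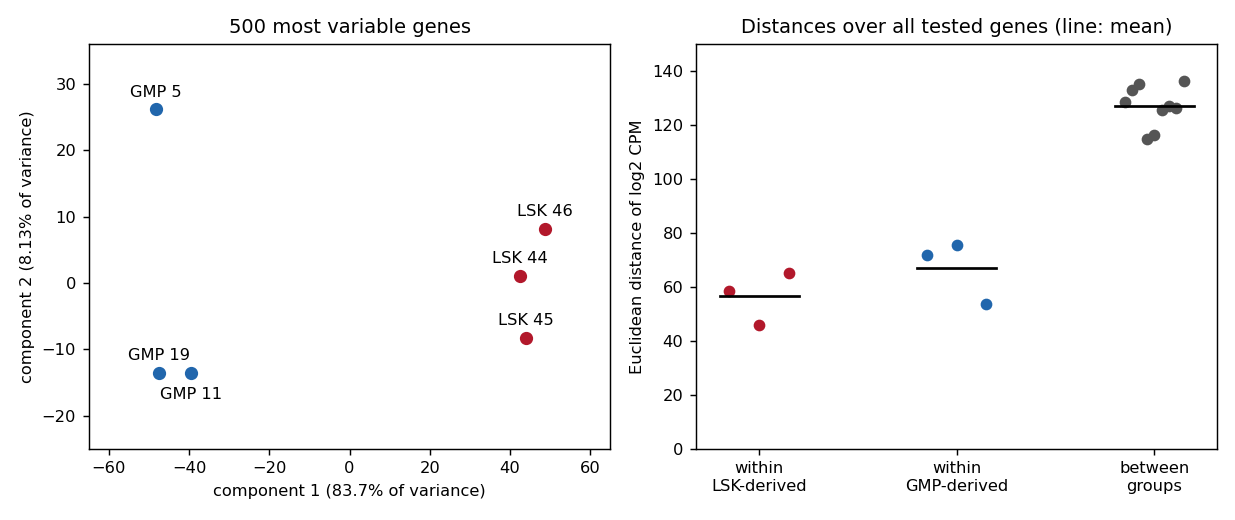
Left, each library on the first and second principal component of log2 CPM, in red for LSK-derived and blue for GMP-derived, with the percentage of variance on the axes. Right, Euclidean distance of log2 CPM over all tested genes for each pair of libraries, with a line at the mean; the means are 56.5 within LSK-derived, 67.0 within GMP-derived and 127 between groups.

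Mecom, which encodes the stem cell transcription factor EVI1, was at 170 ± 22.8 CPM in the LSK-derived and 0.0787 ± 0.0681 CPM in the GMP-derived libraries, where it had 8 counts in all (log2 fold change 10.87 ± 0.31, adjusted p = 4.72e-05). Hlf, another stem cell transcription factor, was at 15.5, 16.6 and 88.3 CPM in LSK 44, LSK 45 and LSK 46 and at most 0.178 CPM in a GMP-derived library (log2 fold change 8.01 ± 1.07, or 6.69 without LSK 46). Its call was lost with limma voom and sample weights (adjusted p = 0.106, the highest in a range from 1.39e-15 over its alternatives). Dsc2 and Dsp, which encode desmosomal proteins, were higher, Dsc2 at 17.3 ± 4.72 against 0.0494 ± 0.0619 CPM and Dsp at 27.3 ± 16.1 CPM against at most 0.246 CPM in a GMP-derived library. Leaving out the GMP-derived library with most of a gene's few counts raised the log2 fold change of Dsc2 from 8.21 to 9.62 (GMP 11), of Dsp from 7.76 to 8.43 (GMP 5), of Lphn2 from 7.12 to 8.11 (GMP 5) and of Arap2 from 7.89 to 12.37 (GMP 11). Arap2 (26.6 ± 3.48 CPM), the adhesion receptor gene Lphn2 (50.2 ± 10.5 CPM) and the globin gene Hbb-b2 (50.2 ± 47.1 CPM) were each below 0.4 CPM in the GMP-derived mean. Of 2 other desmosomal genes, chosen after their values were seen, Pkp2 was higher (3.30 ± 0.967 against 0.509 ± 0.166 CPM, adjusted p = 0.00330) and Pkp3 was lower (2.39 ± 0.885 against 20.3 ± 0.762 CPM, adjusted p = 0.000680). Hbb-b2 was not called with limma voom (adjusted p = 0.0684, or 0.0813 with sample weights, in a range from 7.62e-06). Mycn, a MYC family gene, was at least 177-fold higher on average, with 0 counts in the GMP-derived libraries and 3.93, 0.471 and 12.9 CPM in LSK 44, LSK 45 and LSK 46 (fitted log2 fold change 10.25, or 8.85 without LSK 46). Homer2 had 1 count there, a ratio of 816 (counting interval 147 to 32245), and 9.26, 0.785 and 16.5 CPM in LSK 44, LSK 45 and LSK 46, and the eosinophil peroxidase gene Epx had 2 counts, a ratio of 546 (151 to 4507), and 22.1, 2.63 and 10.8 CPM. Their fitted log2 fold changes were 9.14 (8.31 without LSK 46, 10.88 without GMP 5) and 8.78 (7.99 without LSK 44, 11.30 without GMP 5).

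Col6a3, a collagen VI gene, was at 199 ± 93.0 CPM in the GMP-derived and 0.0749 ± 0.0446 CPM in the LSK-derived libraries, where it had 5 counts (log2 fold change -11.27 ± 0.74, adjusted p = 0.000586; -11.89 without LSK 46). Mlph, a melanosome transport gene, was at 58.9 ± 29.4 against 0.0539 ± 0.0468 CPM, the myelin protein gene Pmp22 at 80.2 ± 98.0 against 0.0997 ± 0.0921 CPM, and the potassium channel subunit gene Abcc8 at 27.1 ± 29.1 against 0.123 ± 0.0845 CPM (log2 fold change -7.75; -6.36 without GMP 19 and -8.46 without LSK 46). Abcc8 was not called with limma voom (adjusted p = 0.111, or 0.0712 with sample weights, in a range from 7.03e-10 over its alternatives). Vcam1, an adhesion molecule gene, was at least 171-fold and Gng11, a G protein subunit gene, at least 111-fold higher in the GMP-derived libraries, with 0 counts in the others. Vcam1 was at 6.11, 1.28 and 15.9 CPM in GMP 5, GMP 11 and GMP 19 (fitted log2 fold change -10.68, or -9.51 without GMP 19), and Gng11 at 2.42, 5.37 and 7.27 CPM. Ratios over 1 to 3 counts were 1364 for the heparanase family gene Hpse2 (counting interval 245 to 53875), 727 for Zcchc3 (131 to 28733), 656 for Gal3st1 (118 to 25901) and 207 for Aldh1a7 (70.7 to 1002). Single libraries moved the fitted log2 fold changes of Hpse2 (-10.02; -12.10 without LSK 45), Zcchc3 (-9.12; -11.19 without LSK 45), Gal3st1 (-8.95; -11.13 without LSK 44), Aldh1a7 (-7.54; -6.85 without GMP 5) and Pmp22 (-9.71; -7.97 without GMP 19). Pmp22 lost its call without LSK 44 (adjusted p = 0.0509), LSK 45 (0.0605) or LSK 46 (0.0639), with no filter (0.0583) and with limma voom (0.194, or 0.0923 with sample weights), in a range from 8.28e-09. The call of Vcam1 was lost in each fit that left out a library except GMP 11 (adjusted p up to 0.0723, without LSK 46), that of Mycn in each except the one without LSK 45 (up to 0.107, without LSK 44), and that of Homer2 without GMP 19 (0.0568). With no filter Vcam1 (adjusted p = 0.143, in a range from 2.94e-06) and Mycn (0.193, in a range from 5.51e-05) were not called, nor Mycn with sample weights (0.0589), nor Homer2 with limma voom (0.0633, or 0.0736 with sample weights, in a range from 2.50e-06).

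In all, 3444 of 13406 tested genes differed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 1577 of them higher in the LSK-derived and 1867 higher in the GMP-derived libraries. Of these, 1478 changed by at least 2-fold (661 higher in LSK-derived, 817 in GMP-derived) and 749 by at least 4-fold (357 and 392). The biological coefficient of variation was 19.4%. The groups did not overlap in 45.4% of tested genes, where chance gives 10%. The count was 1750 without LSK 46 (770 higher in LSK-derived, 980 in GMP-derived) and 1830 without LSK 44 (857 and 973), and 1003 genes passed a test against a 1.5-fold minimum.

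Stem cell genes as a list were higher in the LSK-derived leukaemias, with 8 of 14 tested members higher, 2 lower and 4 not passing (9 and 3 adjusted over the list alone). The list held 24 genes, of which 10 were too low to be tested. Between 6 and 10 members were higher in the fits without a library. The list was called by camera (adjusted p = 0.00932) and by fry (0.00651), and had an adjusted p = 0.663 with an estimated correlation. Besides Mecom and Hlf, the higher members included Angpt1, which encodes a ligand of stem cell niches (229 ± 37.3 against 55.1 ± 11.1 CPM, log2 fold change 2.06 ± 0.18), and Sox4 (26.8 ± 3.49 against 13.9 ± 0.979 CPM). Ly6a, which encodes Sca-1, was higher at a low level (1.83 ± 1.03 against 0.255 ± 0.0840 CPM, adjusted p = 0.00977). The lower members, Mllt3, the fusion partner gene, and Meg3, a long noncoding RNA, lost their calls in fits without a library (adjusted p up to 0.0643 and 0.102). Kit, the SCF receptor gene, was 1.68-fold higher (193 ± 12.0 against 115 ± 24.7 CPM, adjusted p = 0.0134). Cd34 was at 181 ± 17.7 and 150 ± 108 CPM and did not pass (adjusted p = 0.714); without GMP 5, which had 272 CPM, it was called (log2 fold change 1.02, adjusted p = 0.0285).

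MLL fusion targets moved in both directions. Of 26 tested members, 6 were higher in LSK-derived libraries, 12 were higher in GMP-derived ones and 8 did not pass (7 and 13 adjusted over the list alone). Hoxa9, a homeobox gene that MLL fusions activate, was at 191 ± 10.5 CPM in LSK-derived and 328 ± 2.99 CPM in GMP-derived libraries (log2 fold change -0.78 ± 0.06, adjusted p = 0.000682). Hoxa10 showed the same direction (88.7 ± 15.4 against 226 ± 17.9 CPM, log2 fold change -1.35 ± 0.13). Meis1, the HOXA9 cofactor gene, was at 122 ± 8.83 and 120 ± 11.9 CPM and did not pass (log2 fold change 0.03 ± 0.10, adjusted p = 0.863). Bcl11a, a transcription factor gene on the list, was at 2.95 ± 0.880 against 0.0492 ± 0.0453 CPM, the latter from 5 counts (log2 fold change 5.66 ± 0.56, or 6.26 without GMP 11). Without LSK 44 or LSK 46 the count of lower members was 6. The list was not called (camera adjusted p = 0.278), and its median log2 fold change of -0.36 and mean of 0.44 differed in sign, the test following the median.

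Of the LSD1 complex and its recruiting partners, 6 of 18 tested members were higher in the LSK-derived libraries, 2 were lower and 10 did not pass. Kdm1a itself was at 113 ± 7.35 CPM in LSK-derived and 94.9 ± 15.5 CPM in GMP-derived libraries and did not pass (log2 fold change 0.25 ± 0.12, adjusted p = 0.185); without GMP 5 it was called (adjusted p = 0.04004). Its partners Gfi1 and Gfi1b, which recruit LSD1 to DNA, moved apart. Gfi1 was 1.72-fold lower in the LSK-derived libraries (109 ± 18.4 against 187 ± 27.1 CPM, adjusted p = 0.0129), and the tested gene A430072P03Rik overlaps it. Gfi1b was higher (14.8, 7.10 and 32.5 CPM in LSK 44, LSK 45 and LSK 46, against 0.138 ± 0.119 CPM, log2 fold change 6.89 ± 0.89, or 6.17 without LSK 46), with 14 counts in the GMP-derived libraries. The corepressor gene Rcor2 was at 44.3 ± 16.8 against 4.29 ± 1.76 CPM (adjusted p = 0.00370), and Mta1, a nucleosome remodelling complex member, was 1.36-fold higher. Rcor3 was the other lower member, and lost its call without GMP 19 or LSK 44 (adjusted p up to 0.0687). Without LSK 46 the count of higher members was 3. The list was not called by camera (adjusted p = 0.0795), with 0.0243 by fry, 0.0440 with no filter and 0.0298 without genes shared between lists, in a range of 0.0243 to 0.730 over its alternatives.

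Among BCL-2 family genes, Bcl2 showed the largest difference of an abundant member. It was at 156 ± 17.2 CPM in LSK-derived and 40.3 ± 5.81 CPM in GMP-derived libraries (log2 fold change 1.95 ± 0.13, adjusted p = 0.000496). Bcl2l1, which encodes the anti-apoptotic BCL-XL, was 1.61-fold higher (48.1 ± 10.5 against 29.9 ± 1.08 CPM, adjusted p = 0.0193), a call lost without GMP 11 (0.0588) or LSK 44 (0.0615). Mcl1 was at 260 ± 17.3 and 286 ± 22.2 CPM and did not pass (adjusted p = 0.279). Of 14 tested anti-apoptotic members, 3 were higher, 1 was lower and 10 did not pass, and the list was not called (adjusted p = 0.829); its median of -0.09 and mean of 0.05 differed in sign. The remaining called members, Bcl2a1d (higher) and Bcl2a1a (lower), are near-identical copies whose reads may have been divided between them, and both lost their call when single libraries were left out (Bcl2a1a with adjusted p = 0.0531 without LSK 46, Bcl2a1d with 0.118 without GMP 11). Bcl2a1d was also not called by DESeq2 (0.107) or with no filter (0.0577), in a range of 0.02498 to 0.118. Without a library, between 1 and 3 members of the list were higher and between 0 and 2 lower.

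Some pro-apoptotic genes were lower in LSK-derived libraries, without a call for their list. Bax, which permeabilises mitochondria, was 1.59-fold lower (88.3 ± 7.62 against 140 ± 8.82 CPM, adjusted p = 0.00314). Apaf1, the apoptosome scaffold, was 1.64-fold lower (103 ± 6.28 against 169 ± 9.80 CPM), Casp9, the caspase it activates, 1.78-fold lower (46.9 ± 6.00 against 83.7 ± 3.96 CPM), and the executioner caspase gene Casp6 1.64-fold lower (14.7 ± 1.72 against 24.0 ± 1.76 CPM). Bak1 was at 130 ± 6.56 and 155 ± 5.20 CPM (adjusted p = 0.0349), shares exon sequence with the tested gene Ggnbp1, and lost its call with upper-quartile scaling (0.0501) and in 5 of the 6 fits without a library (up to 0.125, without LSK 46; it held without GMP 5). Bcl2l11, which encodes BIM, was at 18.8 ± 1.25 and 24.8 ± 5.17 CPM and did not pass (adjusted p = 0.107). Of 24 tested members, 7 were lower, 3 were higher (among them Casp2 and Diablo) and 14 did not pass (9 and 3 adjusted over the list alone). Diablo lost its call in 5 fits without a library (adjusted p up to 0.101), and the count of lower members was 4 in 5 of those 6 fits. Camera did not call the list (adjusted p = 0.104), with 0.0243 by fry and 0.0479 with no filter, in a range of 0.0243 to 0.730 over its alternatives.

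Targets of p53 were lower as a list by camera (adjusted p = 0.0177) and by fry (0.0243), while Trp53 itself was higher. The list's adjusted p was 0.730 with an estimated correlation and 0.128 without genes shared between lists. Trp53 was at 220 ± 1.36 CPM in LSK-derived and 178 ± 6.45 CPM in GMP-derived libraries (log2 fold change 0.30 ± 0.06, adjusted p = 0.0126; 0.0538 without LSK 46). Cdkn1a, the cell cycle inhibitor gene that p53 activates, was 1.54-fold lower (58.7 ± 8.90 against 90.4 ± 8.42 CPM, adjusted p = 0.0136; 0.0592 without LSK 44). Of 34 tested members, 13 were lower, 2 were higher (Sesn1 and Ak1) and 19 did not pass (14 and 3 adjusted over the list alone), with a median log2 fold change of -0.25. Ak1 lost its call in 4 fits without a library (adjusted p up to 0.0936), and without LSK 44 the count of lower members was 8. Besides Bax and Apaf1, which also stand on the pro-apoptotic list, the lower members included the DNA polymerase gene Polk (21.2 ± 2.10 against 36.5 ± 3.73 CPM) and the T cell costimulator gene Cd80 (0.630 ± 0.175 against 3.70 ± 0.912 CPM).

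**Figure D2:**
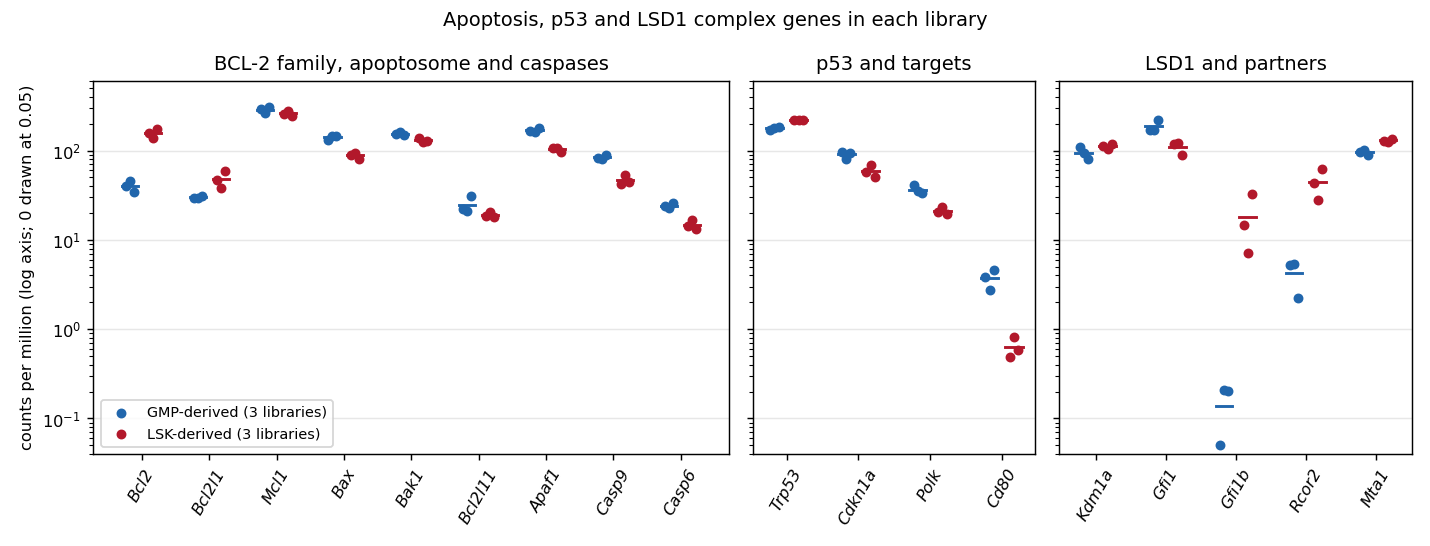
CPM on a log axis for named genes of apoptosis, p53 and LSD1, with 1 point for each of the 3 libraries in a group, blue for GMP-derived and red for LSK-derived, and a line at the group mean; 0 is drawn at 0.05. Bcl2 is at 156 CPM in LSK-derived and 40.3 CPM in GMP-derived libraries, Bax at 88.3 and 140 CPM, and Kdm1a at 113 and 94.9 CPM with overlapping points.

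None of the granule, neutrophil and monocyte lists was called, and members passed in both directions. Of 17 tested granule and progenitor genes, 4 were higher in LSK-derived libraries (Nkg7, Ctsc, Clec12a and Prss57), 5 were lower (Fcgr3, Cebpa, Gfi1, Ctsg and Csf3r) and 8 did not pass (camera adjusted p = 0.829). Cebpa, the transcription factor gene of the granulocyte-macrophage lineage, was 1.78-fold lower (100 ± 23.4 against 178 ± 6.67 CPM, adjusted p = 0.0112), and the Fc receptor gene Fcgr3 was 4.82-fold lower (33.7 ± 14.1 against 163 ± 11.2 CPM). Nkg7 was 16.5-fold higher (42.7 ± 18.9 against 2.57 ± 0.313 CPM) and the lysosomal protease gene Ctsc 1.74-fold higher. Mpo, the myeloperoxidase gene, was at 1010 ± 351 and 277 ± 246 CPM and did not pass (adjusted p = 0.247); GMP 5 had 13.8 CPM, and without it the log2 fold change was 1.30 and the gene was called (adjusted p = 0.0448). Neutrophil genes split into 4 higher (Padi4, Ly6g, Pglyrp1 and Anxa1), 5 lower (Trem1, Stfa1, Cd177, S100a9 and Ngp) and 9 not passing of 18 (5 and 8 adjusted over the list alone; camera adjusted p = 0.912). Padi4, which encodes a histone citrullinating enzyme, was 8.45-fold higher (145 ± 10.5 against 17.1 ± 7.75 CPM). S100a9 was at 195 CPM in GMP 19 and at 5.37 and 20.1 CPM in GMP 5 and GMP 11. Calls lost in fits without a library were those of S100a9 (adjusted p up to 0.160), Ngp (0.163), Stfa1 (0.105), Cd177 (0.140), Trem1 (0.0969), Anxa1 (0.103), Pglyrp1 (0.0760), Ly6g (0.0557), Prss57 (0.116), Ctsg (0.0769), Csf3r (0.0892), Clec12a (0.0555) and Cx3cr1 (0.0665). Not called with no filter were Cx3cr1 (0.0502) and Pglyrp1 (0.0772), and with limma voom Trem1 (0.0561). Without GMP 5, 3 neutrophil genes were higher and 13 lower of 21 then tested, while without GMP 11 or GMP 19 only 1 was lower and without LSK 44, LSK 45 or LSK 46 in turn 0 were. The granule and progenitor counts were 2 and 3 without LSK 44, and 4 monocyte genes were lower without GMP 11. Of 26 monocyte genes, only Cx3cr1 was called higher, Ifi30 and Slc11a1 were lower and 23 did not pass (camera adjusted p = 0.939; the median of -0.24 and the mean of 0.10 differed in sign, and the median was 0.09 without GMP 11 or LSK 46 and 0.21 without GMP 19). Itgam, which encodes CD11b, was at 193 ± 102 and 301 ± 107 CPM and did not pass (adjusted p = 0.293).

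Several receptor genes for myeloid cytokines were lower in the LSK-derived libraries, without a call for their list. Il3ra was 3.45-fold lower (10.9 ± 1.43 against 37.8 ± 8.44 CPM, adjusted p = 0.00148), and Csf2rb, the chain shared by the IL-3, IL-5 and GM-CSF receptors, was 2.08-fold lower (202 against 421 CPM, adjusted p = 0.00498). Tgfbr2 and Ccr1 were 2.15-fold and 2.07-fold lower. Of 29 tested receptors, 9 were lower, 3 were higher (Kit, Flt3 and Il18r1) and 17 did not pass (11 and 5 adjusted over the list alone). Il18r1 lost its call without GMP 19 (adjusted p = 0.0555), and the count of lower members was 4 without LSK 44 or LSK 46. The list was not called with all libraries (adjusted p = 0.0934), and was called without GMP 5 (0.0426) or LSK 45 (0.0420), with the stricter filter (0.0379) and without shared genes (0.0298), in a range of 0.0298 to 0.892 over its alternatives.

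Megakaryocyte and erythroid genes as a list were higher in the LSK-derived libraries by camera (adjusted p = 0.00932; 1.07e-08 without LSK 45). The list was not called by fry (0.144) and had an adjusted p = 0.892 with an estimated correlation. The list held 31 genes. Of 13 tested members, 5 were higher (Vwf, Tal1, Hbb-b2, Car2 and Selp), 0 were lower and 8 did not pass (9 and 0 adjusted over the list alone). Vwf, which encodes von Willebrand factor, was at 3.66 ± 0.582 against 0.512 ± 0.269 CPM (log2 fold change 2.81 ± 0.38). Tal1, an erythroid and stem cell transcription factor gene, was at 3.69, 2.32 and 10.5 CPM in LSK 44, LSK 45 and LSK 46 and at most 0.148 CPM in a GMP-derived library (log2 fold change 6.12 ± 0.92; 5.24 without LSK 46 and 7.15 without GMP 11). Hbb-b2 was at 33.2, 14.0 and 104 CPM in the same libraries (log2 fold change 8.51 ± 1.28; 7.38 without LSK 46, 7.87 without GMP 11 and 11.33 without GMP 5), and its reads may be shared with other beta-globin genes. Car2 was at 3.89 ± 2.71 against 0.472 ± 0.234 CPM and lost its call in 4 of the 6 fits without a library (adjusted p up to 0.0959, without GMP 19), and Selp in all 6 (up to 0.108). Hbb-b2 and Car2 were not called with limma voom (0.0684 and 0.0815) or with sample weights (0.0813 and 0.0540). The filter kept 13 members without LSK 44 or LSK 46, of which 3 were higher, and 21 without each of the other libraries, of which 3 were higher without GMP 11, 4 without GMP 19, 9 without GMP 5 and 14 without LSK 45.

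None of the other lineage lists was called. Many of their members were too low to be tested. The lists held 21 mast cell and basophil, 20 B cell, 22 T and NK cell, 22 dendritic cell and 23 stromal genes. Of 8 mast cell and basophil genes, 3 were higher (Mcpt8, Epx and Prg2), 2 were lower (Hdc and Srgn) and 3 did not pass (camera adjusted p = 0.695, with median -0.03 and mean 0.84). Their median was 1.103 without GMP 5, 0.75 without GMP 11, 0.67 without GMP 19 and 0.80 without LSK 45, with 10 members then tested. Mcpt8, a basophil protease gene, was 2.33-fold higher (30.6 ± 1.13 against 13.1 ± 1.96 CPM), and Hdc, the histamine-forming enzyme gene, was lower (10.2 ± 2.39 against 102 ± 72.1 CPM, log2 fold change -3.31 ± 0.53; -2.57 without GMP 5). Of 8 B cell genes, Cd79b was higher (18.1 ± 3.73 against 5.45 ± 2.07 CPM), Vpreb3, Blnk and Igll1 were lower, and 4 did not pass (camera adjusted p = 0.572). Of 7 T and NK cell genes, Klrb1c alone was higher, with a ratio of 33.8 over 2 counts (counting interval 9.37 to 279), and 6 did not pass (camera adjusted p = 0.965, with median -0.14 and mean 0.54). Of 16 dendritic cell and MHC class II genes, 5 were higher (H2-Aa, Ciita, H2-Eb1, Flt3 and Ccr7), H2-DMb1 was lower and 10 did not pass (camera adjusted p = 0.2). H2-Aa was at 3.89 ± 0.895 against 0.576 ± 0.225 CPM, and H2-DMb1 at 18.1 ± 1.85 against 39.2 ± 3.05 CPM. Of 8 stromal genes, Col4a2 was higher, Acta2 (0.358 ± 0.0868 against 4.62 ± 0.841 CPM) and Pdgfrb (2.63 ± 2.17 against 26.9 ± 11.6 CPM) were lower and 5 did not pass (camera adjusted p = 0.660). The stromal median of -0.36 was 0.18 without GMP 19. Calls lost in fits without a library were those of Prg2 (adjusted p up to 0.0801), Srgn (0.109), Vpreb3 (0.0628), Blnk (0.0617), Igll1 (0.127), Ccr7 (0.136), Col4a2 (0.0649) and Pdgfrb (0.0823). With no filter Prg2 (0.0680), Igll1 (0.0849) and Pdgfrb (0.0743) were not called, nor were Prg2 (0.0503, or 0.0589 with sample weights) and Igll1 (0.125) with limma voom. Without LSK 46, 0 B cell genes were lower, and in fits without a library 2 to 4 mast cell and basophil genes were higher and 1 to 3 stromal genes lower.

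Interferon-stimulated genes as a list were lower in the LSK-derived libraries by camera (adjusted p = 0.00932), with 0 higher, 8 lower and 22 not passing of 30. The list was not called by fry (0.277), and its adjusted p was 0.892 with an estimated correlation. Ifih1, an RNA sensor gene, was 2.29-fold lower (19.8 ± 1.96 against 45.5 ± 11.7 CPM, adjusted p = 0.00606), Oas1a 2.01-fold lower and Stat2 1.45-fold lower. Without LSK 44 or LSK 46 the count of lower members was 5. Of 30 MYC and ribosome biogenesis genes, 6 were higher, Ldha was lower and 23 did not pass. Myc was 1.78-fold higher (317 ± 10.8 against 178 ± 20.3 CPM, adjusted p = 0.00191), and Mybbp1a, which regulates ribosomal RNA synthesis, 1.48-fold higher (763 ± 70.7 against 516 ± 61.5 CPM; adjusted p = 0.0121, or 0.0505 without LSK 44). Ldha lost its call in 4 fits without a library (adjusted p up to 0.102), and the count of higher members was 1 without LSK 44 and 2 without LSK 46. The share of counts in ribosomal protein genes was 5.27% ± 0.111 in LSK-derived and 4.76% ± 0.0601 in GMP-derived libraries (exact permutation p = 0.1, two-sided, the smallest possible). Camera called this list (adjusted p = 0.00132) and fry did not (0.257), and its adjusted p was 0.892 with an estimated correlation. Endoplasmic reticulum and integrated stress genes had 0 members higher, 7 lower and 13 not passing of 20. Atf4, the transcription factor gene of the integrated stress response, was 1.37-fold lower (491 ± 14.7 against 673 ± 30.3 CPM, adjusted p = 0.00384). Between 2 and 5 members were lower in the fits without a library. That list was called by camera (adjusted p = 0.0246) and fry (0.0243), lost its call without GMP 11 (0.0763), without LSK 46 (0.0664) and with length and GC trends removed (0.0720), and had an adjusted p = 0.698 with an estimated correlation.

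Few proliferation genes passed. Of 36 S-phase and mitotic genes, Cdk1 was higher, 5 were lower (Bub1b, E2f1, Cdc45, Mki67 and Ccne1) and 30 did not pass (0 and 4 adjusted over the list alone; camera adjusted p = 0.965, with median and mean of different sign, and a median that turned without GMP 19, LSK 44 or LSK 46). Mki67 was 1.28-fold lower (547 ± 48.3 against 702 ± 34.2 CPM, adjusted p = 0.0216), a call lost without GMP 11 (0.0640) or LSK 44 (0.0645). Of 18 NF-kB and inflammatory genes, Nfkb1 was higher, 5 were lower (Icam1, Ccl4, Ccl3, Il1rn and Bcl3) and 12 did not pass (1 and 6 adjusted over the list alone; camera adjusted p = 0.278). Icam1, an adhesion molecule gene, was 2.56-fold lower (14.2 ± 3.37 against 36.3 ± 4.84 CPM), and the chemokine gene Ccl4 11.6-fold lower (1.31 ± 0.749 against 15.6 ± 7.26 CPM). Of 17 immediate early genes, Egr1 was higher, Atf3 and Fos were lower and 14 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.572). Calls lost in fits without a library were those of Cdk1 (adjusted p up to 0.145), Bub1b (0.0709), E2f1 (0.0728), Cdc45 (0.0914), Ccne1 (0.128), Ccl3 (0.0628), Il1rn (0.0786), Bcl3 (0.128), Egr1 (0.0858) and Fos (0.127). Ccl3 was also not called with no filter (0.0596) and Fos with limma voom (0.139, in a range from 0.00177). Without GMP 5, 6 immediate early genes were lower and 0 higher (camera adjusted p = 0.1), against 1 lower without each other library in turn. Without a library, between 0 and 4 cell cycle genes and between 2 and 6 NF-kB genes were lower, and without LSK 45, 3 cell cycle genes were higher. Together, camera called 6 of 22 lists, 3 in each direction; none was called with an estimated correlation, and fry called 5. At an unadjusted p below 0.05, camera with an estimated correlation gave the stem cell list (p = 0.0301).

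**Figure D3:**
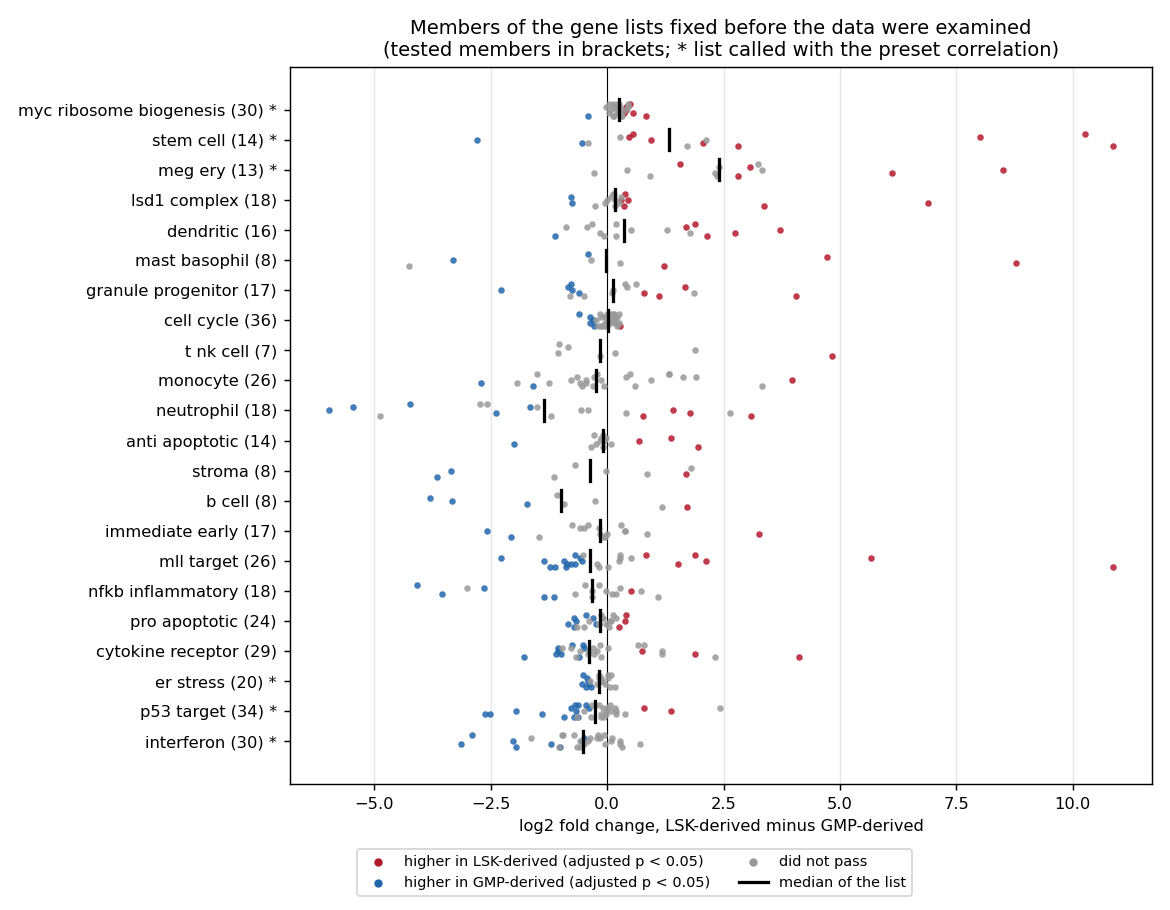
Log2 fold change of each tested member of the 22 lists, LSK-derived minus GMP-derived, in red where called higher in LSK-derived, blue where called higher in GMP-derived and grey where not passing, with a black line at the list's median. Stars mark the 6 lists that camera called with the preset correlation; the p53 target median is -0.25, and fitted values of genes with few counts in a group are not bounds.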

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

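Thinning to the smallest library and removal of length and GC trends were chosen after seeing the data; the other alternatives were fixed before. Of 1389 comparisons of 108 named genes with an alternative, 1253 kept direction and side of the threshold, 128 were weaker, 5 stronger and 3 reversed. No called gene reversed, and 34 of the 100 called genes lost their call in at least 1 fit without a library, 18 under another alternative (up to 0.194, for Pmp22 with limma voom). The gene count stayed between 3073 and 4286 with other scalings, filters, tools and thinning. A minimum of 1.5-fold gave 1003 genes (453 higher in LSK-derived, 550 in GMP-derived) and an adjusted p below 0.01 gave 1297 (555 and 742), each by construction stricter. Without 1 library the count ran from 1750 to 3467 (770 to 1523 higher in LSK-derived, 973 to 1944 in GMP-derived), with fewer samples in each fit. No paired analysis was possible because the groups share no replicate number. The sex covariate was not run, since all libraries carried Xist. Depth limits genes near 0 counts most: 3 counts are 0.180 CPM in LSK 44.

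The causes of the following differences were not tested. With an estimated correlation 0 lists were called, with an adjusted p of 0.663 for stem cell genes and 0.730 for p53 targets, which had 0.128 without shared genes; the called lists numbered 5 to 7 without 1 library. Fry gave 0.0243 for pro-apoptotic genes and for the LSD1 complex, against 0.0479 and 0.0440 with no filter, and the LSD1 complex had 0.0298 without shared genes. Lists that were not called and turned direction were anti-apoptotic (0.436), neutrophil (0.878), T and NK cell (0.530) and cell cycle (0.919) with fry, monocyte and cell cycle with no filter (0.751 each), and monocyte (0.909) and neutrophil (0.891) with the stricter filter. Without 1 library the adjusted p ran from 0.388 to 0.959 for monocyte, 0.802 to 0.98 for T and NK cell and 0.317 to 0.934 for cell cycle genes, with turns of direction. The log2 fold change of Meis1 ran from -0.0549 to 0.0831 and that of Cd34 from -0.0803 to 1.02 without 1 library. The first component held 72.7% of the variance over all tested genes, 76.8% over 2000 genes, 78.5% after variance stabilisation and 80.3% to 87.4% without 1 library. The median SD over genes of at least 10 CPM was 0.125 in GMP-derived and 0.0983 in LSK-derived libraries. Over all tested genes, without 1 library, it was 0.118 to 0.162 and 0.0966 to 0.124.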

Other observations

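The genes in this paragraph were chosen after their values were seen. Some integrin genes moved in opposite directions. Itga4 (705 ± 144 against 256 ± 43.2 CPM, log2 fold change 1.46 ± 0.18) and its partner Itgb7 (64.5 ± 13.9 against 19.7 ± 1.24 CPM) were higher in the LSK-derived libraries. The leukocyte integrin genes Itgal (56.9 ± 6.97 against 120 ± 15.5 CPM) and Itgb2 (132 ± 15.0 against 469 ± 85.7 CPM, log2 fold change -1.83 ± 0.15) were lower. Itgam and Itga2b did not pass (for Itga2b, edgeR adjusted p = 0.127), and integrin genes were not tallied as a list. The 5-methylcytosine oxidase gene Tet1 (7.99 ± 1.11 against 0.871 ± 0.370 CPM) and the DNA methyltransferase gene Dnmt3b (44.9 ± 13.3 against 15.2 ± 3.08 CPM) were higher. Dnmt3l, which encodes a methyltransferase cofactor, was lower (5.13 ± 1.11 against 20.7 ± 1.25 CPM). Genes of DNA methylation were not tallied as a list. Each gene given in this paragraph as higher or lower stayed called in all 6 fits without a library.

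Single libraries stood apart in some lineage genes, also chosen after their values were seen. The megakaryocyte genes Gata1 and Itga2b were at 8.16 and 73.1 CPM in LSK 46, at 3.45 and 28.7 CPM in LSK 44 and at 0.157 and 9.30 CPM in LSK 45 (adjusted p = 0.0861 and 0.127 between groups). GMP 5 had 65.5 CPM of the neutrophil elastase gene Elane, against 815 and 1562 CPM in GMP 11 and GMP 19, and 88.5 CPM of the mast cell gene Cpa3, against 0.683 and 0.968 CPM. GMP 19 had 192 CPM of S100a8, a late granulocyte gene, against 4.92 and 23.0 CPM in GMP 5 and GMP 11.

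For the lower p53 target list, depth, length and GC content, and a single library were weighed, with the predictions written before these tests and the list fixed before the data were examined. Thinned to the smallest library (lower sequencing depth of the LSK-derived libraries), the list stayed called in 20 of 20 draws, with medians from -0.276 to -0.187. Removal of the trends (transcript length and GC content bias between the groups) left a median of -0.224, and the fit nearest 0 of the 6 without a library (a single deviating library) had -0.148. All 3 results met the predictions written against these explanations, the single-library fit by a cut-off of -0.126. Thinning leaves expected fold changes unchanged, so the draws could hardly move the median and say little on depth. The adjusted p of 0.730 with an estimated correlation leaves open whether the list's shared variation accounts for its call. That setting also has fewer degrees of freedom. By camera, the stem cell list rose from p = 0.00170 to 0.0301 with an estimated correlation of 0.00209, below the preset 0.01. A biological difference by cell of origin was not tested apart from the groups themselves.

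The number of genes called was compared with all 10 splits of the 6 libraries into 3 and 3, a test planned before the data were examined. The real split called 3444 genes and was the 1 split with a count as large, and the highest count in another split was 0. With 10 splits a share below 0.05 cannot be reached. Each other split mixes libraries of both groups, so the group difference adds to the spread on each side and works against gene calls. Its sides also hold unequal shares of the groups, so list calls there are not free of the group difference. These splits therefore cannot stand for libraries without a group difference. For lists, the real split called 6 and 5 splits called at least as many, the highest other being 14, in the split of GMP 5, LSK 45 and LSK 46 from the rest. The p53 targets were called in 2 of the 9 other splits, stem cell genes in 1, interferon genes in 6, MYC and ribosome biogenesis genes in 5, and megakaryocyte and erythroid genes and endoplasmic reticulum stress genes in 3 each. For the p53 targets, the lowest camera adjusted p in another split was 0.0153, against 0.0177 in the real one.

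Neighbouring genes were often called in the same direction, a pattern looked at after seeing the calls, with tests devised then. Of 12921 neighbour pairs in reference gene order, 671 were called in the same direction, against a mean of 446 and at most 501 in a permutation test of 1000 shuffles within chromosomes (p = 0.001, the smallest possible). Without exon overlap (reads shared between overlapping genes) 622 pairs remained, against at most 476, and with different first letters (reads shared between neighbouring paralogues) 618, against at most 503. Shuffling within expression deciles (power to call a gene shared by neighbours of like expression) gave at most 513. The shuffles within expression deciles went against shared power. The other checks cannot decide on shared reads. Exon overlap came from another annotation than the counting, and comparing first letters passes interleaved families such as Klrb1 and Clec2 as unrelated. Cell of origin was not tested as a cause. The densest runs of 20 genes held 11 higher in LSK-derived libraries from Fkbp4 to Gabarapl1, with several Klrb1 and Clec genes of uncertain counts. In GMP-derived libraries 10 were higher from Mcm3ap to Trappc10, with Itgb2 and Dnmt3l.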
